A study of Drosophila melanogaster with 8 samples.

How the data were processed

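The samples were 4 Yb CLIP libraries and 4 libraries of Piwi-bound small RNAs from ovarian somatic cells. Groups were taken from the labels. Per the labels' protocols, cells for CLIP were irradiated with ultraviolet light before immunoprecipitation of Yb. Per the submitters' processing notes, the genome build was dm3; the aligner, the trimming and the mapping filter are not given in the sources used here. Each deposited CLIP file lists one sequence per line without a number. No sequence is repeated within a file and all are 30 to 50 nt long, so the values used are counts of distinct tags, which saturate for abundant RNAs. Each deposited Piwi file lists a sequence with its raw read count, with lengths of 20 to 30 nt and no count under 100. A few listed sequences contain an unread base (4 or 5 per library). The data were planned as read counts per gene; because the deposited files hold sequences and no genome was used, the features became contigs and the CLIP unit became the distinct tag.

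Contigs were built from the pooled sequences of all 8 libraries, without use of the groups. Words of 21 nt seen at least 2 times were extended on their own strand to the commonest next base, starting from words seen at least 3 times, and an extension stopped where the second base had more than 0.67 of the support of the first. Contigs of at least 80 nt were kept, which gave 4201 contigs with 726239 nt in all and a longest of 3395 nt. Tags and small RNAs were mapped to the contigs with bwa 0.7.19 (mem, seed of 15, minimum score of 20) and read with samtools 1.23.1. Of the tags, 59.1, 58.5, 56.0 and 55.1% mapped in the sense direction (untreated 1 and 2, non-deleted, deletion 1), and of the Piwi reads 74.7, 62.4, 65.7 and 72.7% (non-deleted, deletion 1, deletion 2, EGFP). A contig is a stretch of RNA, not a gene, and 1 transcript can give several contigs.

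The choice of the tj candidate contig followed a look at the data. Small RNAs that were lower in both Piwi deletion libraries were extended into longer sequences, and the one with the largest loss was then seen to hold a gap in Yb tags. A rule was written after that: the contig with the lowest ratio of deletion 1 to non-deleted CLIP tags among 50-nt windows with at least 50 tags, with the block as its longest stretch under a coverage ratio of 0.1. Contigs were also built with other word lengths, and 21 nt was kept because it gave the candidate in 1 piece. Contigs were classed by their sequence alone. A long open reading frame had at least 450 nt without a stop codon on the sense or the antisense strand, and a retroelement motif was a match to conserved reverse transcriptase and RNase H peptides. Sequences of rRNA, tRNA, small nuclear RNA, long terminal repeats, plasmid parts, EGFP and microRNAs were written from general knowledge and matched by words of 16 nt (microRNAs by their first 19 nt, EGFP and plasmid parts also by shorter words). The classes, their limits and these matches were chosen after the data had been seen, and long terminal repeats recalled with less certainty were left out. The set of sense-coding contigs low in deletion 2 was chosen by that ratio, and the limits for calling opposite changes were set at the same stage. The count of opposite changes by intervals and the comparison of changed contigs with the EGFP library were added later, after the results were seen. So were the repeats of these counts and of the leading contigs without 2S rRNA or with unlisted sequences at 99 reads, the same repeats for the sense-coding contigs, and the comparison of the non-deleted and untreated CLIP libraries on the contigs of the deletion comparison.

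Values were scaled to the total of all deposited tags or reads of the library (CPM). Ratios of 2 counts have exact conditional binomial intervals, counts have exact Poisson intervals and shares have exact Clopper-Pearson intervals, all at 95% and all for counting error only, since copies from amplification were not told apart in the read counts. A contig counted as changed with at least 50 reads in a library and a ratio over 2. Contigs were named by a rule fixed in advance: the 10 with most reads or tags in the control, and up to 10 each way with the largest fold whose interval excluded 1 and whose direction was the same in both Piwi deletion libraries, or against each of the 3 undeleted CLIP libraries. For the Piwi libraries the fold was the smaller of the 2 bounds obtained with unlisted sequences at 99 reads, a change made after the limit of 100 reads had been seen. Unchanged Piwi libraries were simulated with Poisson counts and the limit of 100 reads (20 draws), with unlisted sequences at 50 reads in the pooled rate. Lists were compared with 10000 random lists of the same size, matched in 10 classes of level. Log2 CPM of tags used a pseudocount of 0.5.

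The calling step was tested on simulated data. With 200 contigs changed, 100% of 4-fold changes and 98% of 3-fold falls were called among the 1115 contigs of the Piwi comparison, and 100% and 96% among the 930 contigs of the Yb comparison, with 0% of unchanged contigs called. The simulation had no limit on listed reads and held counting noise only, with no spread between libraries. All planted changes lay beyond the limit of 2-fold. It therefore checks the calling step and does not measure false calls in the real libraries. Alternatives chosen before the data were examined were other read minimums, scalings, ratio thresholds, controls and length classes. Alternatives added after seeing the data were word lengths of 19 and 23 nt, a minimum of 1000 reads and Yb tags outside the block. Others added then were totals without 2S rRNA, totals of the antisense-coding contigs, unlisted sequences at 99 reads, and this together with totals without 2S rRNA. Values for flam, for the 3' UTR of tj and for the fixed lists of genes and of most transposons were left out because they need a genome. Analyses used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.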

Results

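The series profiled RNA bound by 2 proteins of the piRNA pathway in ovarian somatic cells (OSC), a cultured line of follicle-like cells from the Drosophila melanogaster ovary. Yb is a Tudor-domain RNA helicase-like protein of the perinuclear Yb body, and Piwi is the nuclear Argonaute protein that carries PIWI-interacting RNAs (piRNAs) in these cells. Yb was crosslinked to RNA with ultraviolet light and immunoprecipitated (CLIP) from untreated cells (n = 2), from non-deleted cells (n = 1) and from cells that lack a cis-element of tj (n = 1). Small RNAs bound to Piwi were sequenced from non-deleted cells, from 2 tj deletion lines and from cells that express an EGFP artificial piRNA, with n = 1 each. The gene tj (traffic jam) encodes a large Maf transcription factor of gonadal somatic cells and is known as a genic source of piRNAs. The design asks whether removal of the element changes Yb binding to tj RNA and the piRNAs made from it. The labels number the 2 Piwi deletion libraries 1 and 2, and they are read here as separate lines. On that reading no deletion comparison has a replicate, so ratios are given with exact 95% intervals that cover counting error only, and no p-value is given.

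The Yb CLIP libraries listed 1943270 and 1942833 distinct tags (untreated), 610416 (non-deleted) and 437789 (deletion 1), each 30 to 50 nt long. Each tag stands once, so a value is a number of distinct tags, not of reads. The Piwi libraries listed 15927 sequences with 12703689 reads (non-deleted), 13418 with 10263036 (deletion 1), 11918 with 9276418 (deletion 2) and 7348 with 5075716 (EGFP artificial piRNA). No sequence had fewer than 100 reads, so a Piwi value of 0 means that no sequence reached 100 reads. These totals are sums of the listed sequences and not sequencing depths. The files hold sequences without gene names and no genome sequence was used here, so overlapping tags and small RNAs of all libraries were joined into 4201 contigs, which serve as the features below and are named ctg followed by a number. Gene-level values for flam and for the protein-coding genes fixed in advance were therefore not analysed here. Tags and reads scaled to the total of their library are given as CPM.

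The Piwi-bound small RNAs had the size and the first base of piRNAs in every library. Without 2S ribosomal RNA the commonest length was 27 nt in all 4 libraries, at 29.08% (non-deleted), 27.12% (deletion 1), 27.95% (deletion 2) and 30.97% (EGFP) of reads. Uridine stood first in 85.6% of all reads in the non-deleted library (exact 95% interval 85.57 to 85.61%), 86.2% in deletion 1, 86.0% in deletion 2 and 87.2% in the EGFP library. Since 2S rRNA starts with U and its share differed, the order of the first 3 turned without it, to 83.1, 81.4, 81.9 and 84.3%. Reads of 24 to 30 nt made up 94.0, 93.3, 92.7 and 95.6% in the same order, and 93.01, 90.99, 90.61 and 94.56% without 2S rRNA. The 30-nt 2S rRNA, a small insect ribosomal RNA that often contaminates small RNA libraries, was the most abundant sequence and took 14.8, 25.9, 22.8 and 18.6% of the reads. The most abundant other sequence, TATGAGGATCAGACAGTTTTAGTTAAC, had 781435 reads in the non-deleted library, 436287 in deletion 1, 507148 in deletion 2 and 364576 in the EGFP library.

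**Figure D1:**
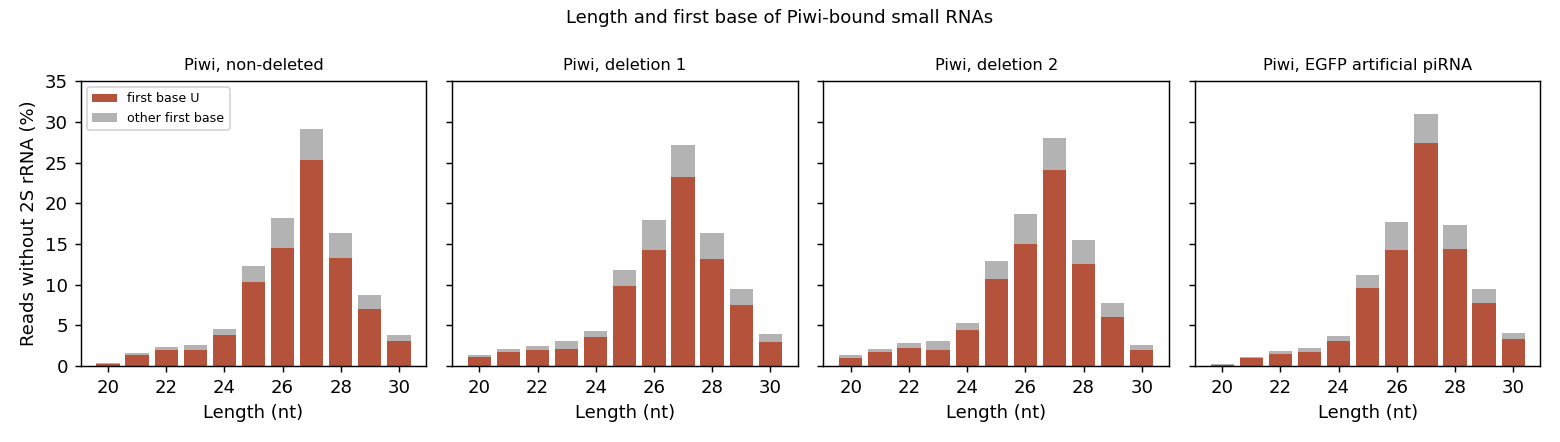
Length (x axis, nt) of Piwi-bound reads without 2S rRNA as a share of reads (y axis, %), split by first base, one panel per library. The peak lies at 27 nt in all 4 libraries and most reads start with U.

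The contig taken as tj was first noticed because its small RNAs were lower in both Piwi deletion libraries, and it was then seen to hold a gap in Yb tags. The scan of Yb tags given here was written after that, so its outcome was known and it adds no independent support. Among 2067 windows of 50 nt with at least 50 tags in non-deleted cells, the window with the deepest loss in deletion 1 was position 151 to 200 of ctg27 (4 tags against 254, a scaled ratio of 0.0220). The second was the neighbouring window, 101 to 150 (2 against 113, 0.0247), and the next window, on ctg316, had a ratio of 0.0832. Ctg27 is 1350 nt long, has no long open reading frame and carries tags on its sense strand, and is called the tj candidate contig below. That it comes from tj rests on these losses and on the labels, not on a match to the genome. The stretch in which coverage in deletion 1 stayed under 0.1 of non-deleted coverage ran over 92 nt, from position 124 to 215, and is called the block. Its sequence is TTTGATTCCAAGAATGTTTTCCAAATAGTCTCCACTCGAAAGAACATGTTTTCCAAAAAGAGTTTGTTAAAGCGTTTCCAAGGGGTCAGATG. Tags that overlap it numbered 639 and 644 in the untreated libraries (328.8 and 331.5 CPM), 370 in non-deleted cells (606.1 CPM) and 9 in deletion 1 (20.56 CPM). The ratio of deletion 1 was 0.0339 to non-deleted (0.0154 to 0.0651), and 0.0625 and 0.0620 to the untreated libraries. Since the block was chosen by low coverage in deletion 1, a low ratio was built in. The interval does not allow for that choice. That the block is the deleted element was not shown.

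Yb tags were lower along the whole candidate contig in the deletion library, not only in the block. The contig held 4354 and 4280 tags in untreated cells (2241 and 2203 CPM), 1275 in non-deleted cells (2089 CPM, 1976 to 2207) and 225 in deletion 1 (514 CPM, 449 to 586). The ratio of deletion 1 to non-deleted was 0.246 (0.213 to 0.284), and it was 0.229 and 0.233 against the untreated libraries, while those differed from each other by a ratio of 0.983 (0.942 to 1.03). Outside the block, 905 tags in non-deleted cells compared with 216 in deletion 1, a ratio of 0.333 (0.286 to 0.387). Against the untreated libraries the ratio outside the block was 0.258 and 0.264. None of the libraries measures the level of the RNA itself, so less Yb binding cannot be told apart from less RNA. In windows of 100 nt, the ratio was 0.0228 at positions 101 to 200, 0.332 at 301 to 400 and 0.469 at 601 to 700. The undeleted libraries differed in where the tags lay. Positions 301 to 400 held 1247 and 1180 tags in the untreated libraries and 601 and 604 tags stood at 101 to 200, whereas in non-deleted cells 214 and 367 tags were found in these windows.

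Piwi-bound small RNAs of the candidate contig were also lower, in both deletion lines. Since the contig was first noticed by this fall, the fall is not an independent test of it. Non-deleted cells held 31505 reads on the contig (2480 CPM, 2453 to 2508), deletion 1 held 7843 (764 CPM, 747 to 781) and deletion 2 held 4793 (517 CPM, 502 to 532). The ratio to non-deleted was 0.308 (0.301 to 0.316) in deletion 1 and 0.208 (0.202 to 0.215) in deletion 2. The EGFP library, whose tj is not stated to be deleted, had 12862 reads (2534 CPM, 2490 to 2578), a ratio of 1.02 (1.00 to 1.04). All reads ran in the sense direction. Of 66 different sequences found on the contig, 44 were under 100 reads in deletion 1 and 53 in deletion 2. If each of those had 99 reads, the ratios would be 0.479 and 0.436, a fall of 2.09-fold and 2.29-fold. With 2S rRNA also left out of the totals they would be 0.551 and 0.482, a fall of 1.81-fold and 2.08-fold.

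Most of these reads came from one place downstream of the block. Positions 501 to 600 held 20886 reads in the non-deleted library, 6472 in deletion 1, 4189 in deletion 2 and 8748 in the EGFP library, with scaled ratios to non-deleted of 0.384 and 0.275 in the deletion lines. The most abundant sequence there, TCCGATGAATATCAGTTTGAGAAC at position 531, had 4896, 1245, 1414 and 1740 reads in the same order. A second species, TGCGACAATAAATTCCGATGAATATCAGT at position 518, had 3514, 1519, 802 and 2395 reads. Windows upstream of position 401 held 445, 2061, 719 and 462 reads in non-deleted cells and no listed sequence in either deletion line. Reads outside the block stood at a ratio of 0.336 (0.327 to 0.344) in deletion 1 and 0.227 (0.220 to 0.234) in deletion 2. The window with most Yb tags was 301 to 400 in untreated cells and 101 to 200 in non-deleted cells, and the window with most Piwi reads in each Piwi library was 501 to 600.

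**Figure D2:**
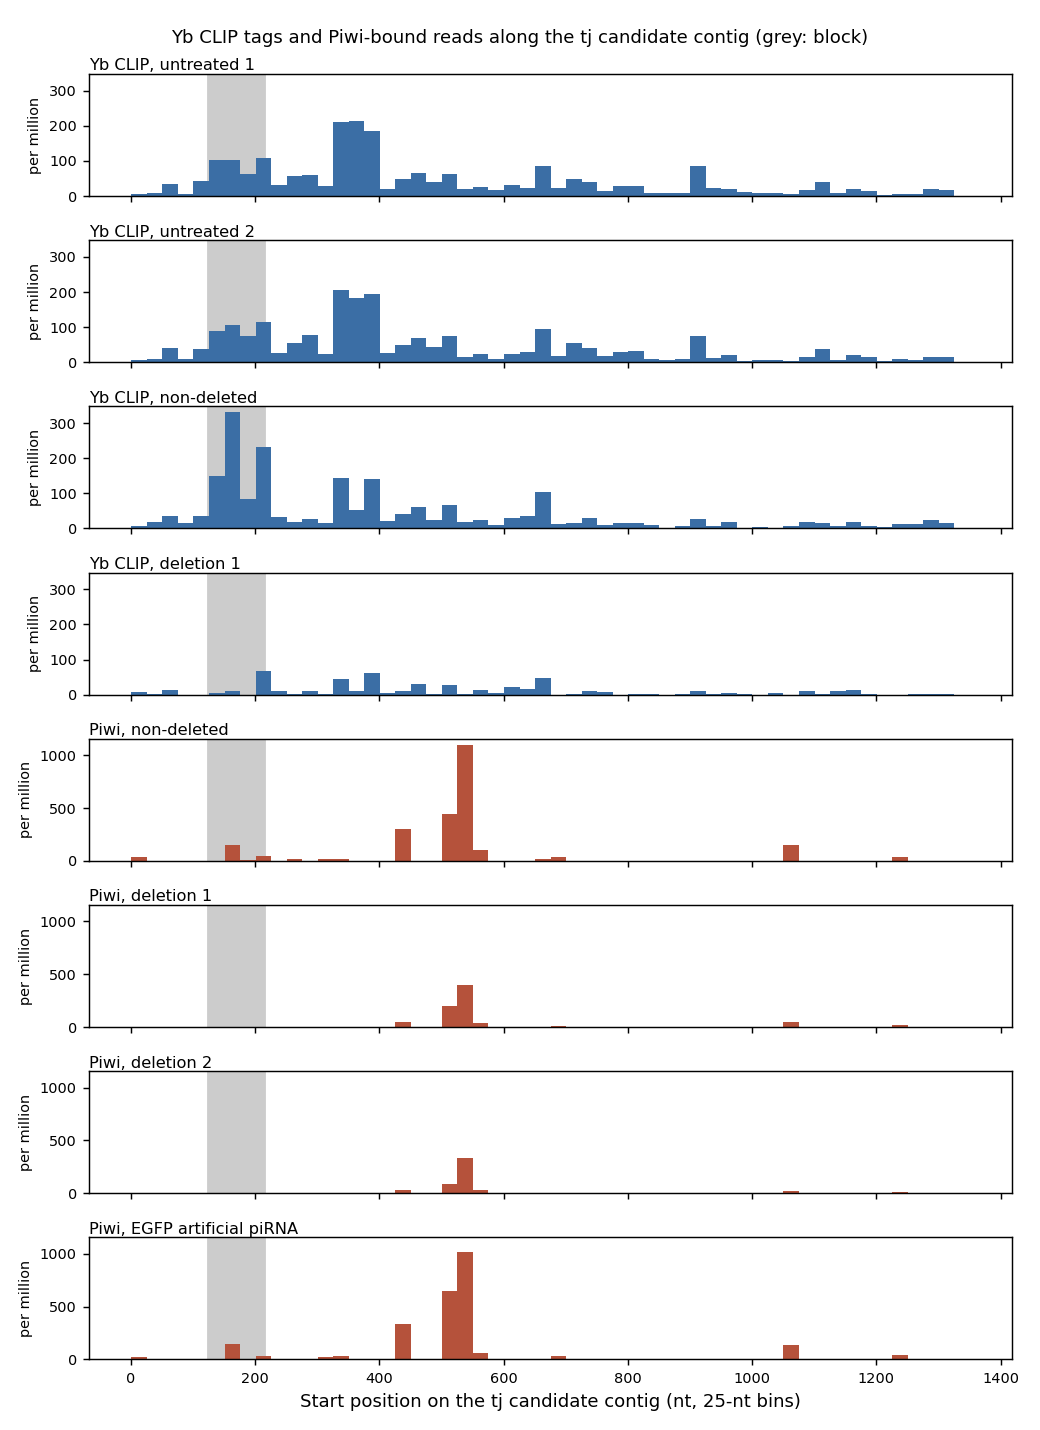
Start positions (x axis, nt, bins of 25 nt) of Yb CLIP tags (blue) and Piwi-bound reads (red) along the tj candidate contig, in CPM (y axis), with the block at positions 124 to 215 in grey. The Yb tags in the block are nearly gone in deletion 1, and the Piwi peak at 501 to 600 is lower in deletion 1 and deletion 2 than in the non-deleted and EGFP libraries.

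Across all contigs each Piwi deletion library differed from the non-deleted one in many places, and fewer contigs were lower or higher in both. The median ratio to non-deleted was 0.856 in deletion 1 and 0.889 in deletion 2. Of 1227 contigs with at least 50 reads, 217 were more than 2-fold lower and 194 higher in deletion 1, and 226 and 147 in deletion 2. The totals include 2S rRNA, at 14.8% of reads in non-deleted cells, 25.9% in deletion 1 and 22.8% in deletion 2. This difference lowers every ratio, so the medians do not show a general fall of piRNAs. The medians and the counts of each single line were not recomputed without it. In both lines, 120 were more than 2-fold lower and 68 more than 2-fold higher, or 111 and 91 with 2S rRNA left out of the totals. Libraries simulated without any change, but with the limit of 100 reads per listed sequence, gave on average 79.1 lower and 0.15 higher contigs, and independent lists would share 40.0 and 23.2. The simulation holds counting noise only and no spread between libraries. Part of the overlap can also come from the control library that both ratios share. In the EGFP library, 101 of the 120 were also more than 2-fold lower than in non-deleted cells, 94 of them without a listed sequence there. Of the 68, 10 were also more than 2-fold higher, while 38 had no listed sequence there and could not be called higher. The limit of 100 reads weighs most in the EGFP library, which has the smallest total. The lower and higher counts can therefore not be set against each other. With at least 1000 reads in a library, 590 contigs remained, of which 12 were lower and 27 higher in both deletion lines. Of these, 6 of the 12 and 6 of the 27 were so in the EGFP library too, while 2 and 6 had no listed sequence there. The tj candidate was among the 12, and only ctg20, with 12772, 3012 and 658 reads in the non-deleted, deletion 1 and deletion 2 libraries, was longer. Ctg20 stood at a ratio of 1.20 in the EGFP library. Further lower contigs were ctg214 (9210, 2147 and 2056 reads, EGFP ratio 0.642) and ctg1489 (2631, 874 and 809 reads), which was as low in the EGFP library, at 0.432 (0.390 to 0.477). Ctg2301 had 1829 reads and ctg3457 had 1120 in the non-deleted library and 702 and 486 in the EGFP library, and neither had a listed sequence in a deletion line.

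When unlisted sequences were set to 99 reads, with 2S rRNA kept in the totals, 7 contigs stayed more than 2-fold lower and 13 more than 2-fold higher in both lines. The candidate stood at rank 6 among the lower ones. With 2S rRNA also left out, it would be 1.81-fold lower in deletion 1, under the limit of 2-fold. Ahead of the candidate stood ctg2755 (5.47-fold and 4.94-fold lower with 2S rRNA in the totals), ctg2301, ctg20, ctg214 and ctg1114, of which ctg1114 had no listed sequence in the EGFP library either. Contigs that were higher included ctg536, with 166 reads in the non-deleted library, 1144 in deletion 1 and 1028 in deletion 2, ratios of 8.53 and 8.48. It was also higher in the EGFP library, at 3.56 (2.91 to 4.37). Ctg1074 went from 374 to 1556 and 1173 reads, and ctg262, named here after its values were seen, from 638 to 10428 and 2238. Ctg262 is not one of the 13, since with unlisted sequences at 99 reads it was 5.81-fold and only 1.38-fold higher. Ctg321 and ctg477 had no listed sequence in non-deleted cells but 577 and 235 reads in deletion 1 and 381 and 618 in deletion 2.

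The 10 most abundant piRNA contigs differed by less than 2-fold between the deletion and non-deleted libraries. The leading contig, ctg277 with 1035467 reads, had ratios of 0.765 in deletion 1 and 0.923 in deletion 2. Ctg8, with 420548 reads and an antisense open reading frame of 1581 nt, had 0.776 and 0.750. For ctg446, ctg13, ctg4, ctg6, ctg30, ctg422, ctg43 and ctg24, the next in order, the ratios lay between 0.628 and 0.923 in deletion 1 and between 0.685 and 1.03 in deletion 2. Without 2S rRNA in the totals the 10 ratios ran from 0.723 to 1.06 in deletion 1 and from 0.756 to 1.14 in deletion 2, and 3 of the 20 ratios changed sides of 1, those of ctg4 in deletion 1 and of ctg277 and ctg43 in deletion 2.

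Contigs with a long open reading frame on the strand opposite to the RNA are called antisense-coding here, without a test that the frame codes for a protein. Such an antisense open reading frame of at least 450 nt was present in 86 contigs. These held 25.02% of the Piwi reads in non-deleted cells, 20.26% in deletion 1, 22.31% in deletion 2 and 23.95% in the EGFP library. The totals include 2S rRNA, at 14.8, 25.9, 22.8 and 18.6% of reads in the same order. The larger 2S rRNA shares by themselves lower the shares of the antisense-coding contigs. Shares without 2S rRNA were not computed, so the lower values are not read as a fall of these piRNAs. The ratios, medians and CPM in this paragraph use the same totals. The antisense-coding contigs had a median log2 ratio of -0.28 in deletion 1 and -0.22 in deletion 2, at the 27.1 and 20.5 percentiles of 10000 random lists of contigs of like level. Protein motifs of retroelement polymerases, from the class of transposons that piRNAs of these cells are known to silence, were found in 19 contigs on the antisense strand and in 2 on the sense strand. Of the 16 motif-bearing contigs that could be compared, none was more than 1.5-fold higher and 3 were lower in deletion 1, with a median log2 ratio of -0.29. In deletion 2, 1 was higher and none lower, with a median of -0.20. These medians lay at the 34.9 and 43.2 percentiles of such random lists. A stretch of the gypsy long terminal repeat was covered by antisense small RNAs with 988 CPM in non-deleted cells, 1468 in deletion 1, 883 in deletion 2 and 1608 in the EGFP library, and by none in the sense direction. Sense small RNAs of the copia long terminal repeat had no listed sequence in the non-deleted and EGFP libraries but 1365 reads in deletion 1 and 511 in deletion 2.

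Contigs with a long open reading frame on their own strand stood apart in deletion 2. In the 15 that could be compared there, 9 were more than 1.5-fold lower and 4 higher, with a median log2 ratio of -2.17, at the 0 percentile of the random lists. The size of this median depends on the limit of listed reads: with unlisted sequences of deletion 2 at 99 reads it was -0.55, with 7 lower and 5 higher, still at the 0 percentile of lists filled in the same way. In deletion 1, 1 of 16 was lower and 7 were higher, with a median of 0.18 at the 99.3 percentile, and among Yb tags 13 of 23 were lower and none higher, with a median of -0.76 at the 0 percentile. These percentiles, like those of the antisense-coding contigs, treat contigs as independent members. Since 1 transcript can give several contigs, a change in a few RNAs could give them. The classes were also chosen after the data had been seen. The longest sense-coding contig, ctg0, held 136791 Piwi reads in non-deleted cells, 80230 in deletion 1, 21358 in deletion 2 and 48223 in the EGFP library.

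**Figure D3:**
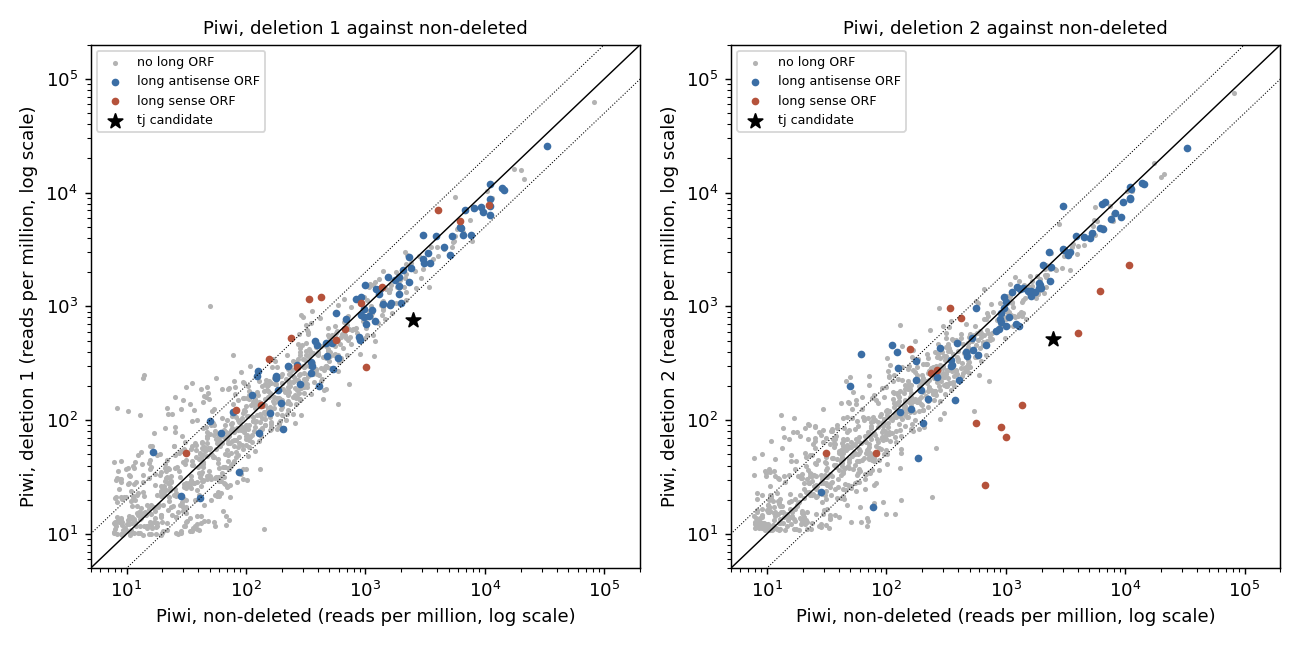
Piwi-bound CPM of each contig in deletion 1 (left) and deletion 2 (right) against the non-deleted library, on log axes, for contigs with reads in both; solid line equal, dotted lines 2-fold. The tj candidate (star) lies below the lower dotted line in both panels, and many contigs with a long sense open reading frame (red) lie below it in deletion 2.

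Most contigs differed less in Yb tags than the candidate did, with a median ratio of 0.996. Of 942 contigs with at least 50 tags, 68 were more than 2-fold lower and 12 more than 2-fold higher in deletion 1 than in non-deleted cells, against 0.4 and 0.15 with counting noise alone. On the same contigs, the 2 untreated replicates differed more than 2-fold in 0 contigs downward and 16 upward. The median absolute log2 ratio was 0.28 between deletion 1 and non-deleted cells and 0.09 between the untreated replicates. The deletion 1 and non-deleted libraries list fewer tags (437789 and 610416) than the untreated ones (1943270 and 1942833). Counting noise is therefore larger in the first median, and part of the difference can come from it. The non-deleted library and untreated replicate 1, neither of which carries the deletion, were further apart, at 0.39 on the same contigs, and the non-deleted library and untreated replicate 2 at 0.35. The direction was the same against all 3 undeleted libraries for 48 contigs more than 2-fold lower and 10 more than 2-fold higher. The candidate ranked 9 among the lower ones. Ahead of it were shorter contigs, led by ctg287 (135 tags against 10), ctg713 (68 against 7) and ctg215 (151 against 20). Of those that were higher, ctg2486 went from 6 to 56 tags, ctg600 from 54 to 101 and ctg70, with an antisense open reading frame of 843 nt, from 359 to 535.

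Several contigs with most Yb tags were also among those with most Piwi reads. The 10 contigs with most tags were the same in both untreated replicates. Ctg4 led with 16876 and 16532 tags, followed by ctg13 (16113 and 15693), ctg8 (15548 and 15330) and ctg6 (14939 and 14553), which are all among the 10 contigs with most Piwi reads. The candidate ranked 35 and 36 by Yb tags and 55 by Piwi reads in non-deleted cells. In deletion 1, the antisense-coding contigs had a median log2 ratio of 0.16, at the 99.7 percentile of 10000 random lists, and those with a retroelement motif had 0.05, at the 44.8 percentile. Of the antisense-coding contigs, 3 of 85 were more than 1.5-fold higher and 2 lower. Contigs matching rRNA, tRNA or small nuclear RNA had a median of -0.77 over 4 contigs, of which 3 were lower. Over all tags that match such RNAs the share was 0.517% in non-deleted cells and 0.473% in deletion 1, and tRNAGlu (642 and 694 CPM) and tRNAGly (614 and 706 CPM) were not lower.

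The untreated Yb CLIP replicates, the only replicated group, were close. Over 2428 contigs, Pearson's r of log2 CPM was 0.979 and Spearman's rho 0.960, the median absolute log2 ratio was 0.13 and 541347 tags were identical in both libraries. Across 2466 contigs, untreated Yb tags and Piwi reads of non-deleted cells had a Spearman correlation of 0.363 (bootstrap 95% interval 0.323 to 0.403). Contigs are not independent replicates, and 1351 of them had no listed small RNA. Per kb of contig the correlation was 0.205. Within the 86 antisense-coding contigs the correlation without scaling to length was 0.635, within the 24 sense-coding ones 0.848 and within the 2356 others 0.281. These class values were not recomputed per kb, so the part that contig length plays in them is not known.

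The library with the artificial EGFP piRNA held no listed read that matched the EGFP sequence used here. That sequence was written from general knowledge and could not be checked, and the EGFP variant and the artificial piRNA of the construct are not known, so the search says little about the construct. Over both strands of the 720-nt EGFP reading frame, 0 sequences matched exactly or with 1 mismatch in any Piwi library, and anything under 100 reads would be unseen. The library did hold 26 sequences with 13604 reads that no other Piwi library listed. Of these, 3 sequences with 8263 reads (1628 CPM) were antisense to the SV40 late polyadenylation sequence, a common part of expression plasmids. Another 16 overlapping sequences with 3611 reads came from a tandem repeat with a period of 25 nt, and 5 sequences, with 957 and 403 reads in their 2 groups, matched a plasmid polylinker over words of 12 nt. For comparison, the largest count of a sequence listed in 1 library only was 470 in the non-deleted library, 1310 in deletion 1 and 636 in deletion 2, against 4533 in the EGFP library.

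MicroRNAs, which are loaded into other Argonaute proteins and so measure the background of a Piwi immunoprecipitate, differed between libraries. The 10 microRNAs searched for summed to 2984 CPM in non-deleted cells, 509 in deletion 1, 3040 in deletion 2 and 966 in the EGFP library. Of these, miR-184 had 2004, 318, 2193 and 657 CPM and miR-275 had 641, 157, 543 and 239. Bantam was listed with 66.4 CPM in non-deleted cells and 23.5 in deletion 2, and in no other library. The 3 microRNAs that could be compared in deletion 1 had a median log2 ratio of -2.70, at the 0 percentile of 10000 random lists of sequences, and the 6 in deletion 2 had -0.19, at the 28.6 percentile. MiR-8, miR-279 and miR-13b were listed in none of the libraries.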

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

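The tests in this part were chosen after the results were seen. In 2 of 54 contigs of at least 1000 nt and 1000 Piwi reads in a library, one deletion line stood at a ratio under 0.8 to non-deleted cells and the other above the inverse of 0.8. These limits were set after the data were seen. With 1 library per line the difference was not tested, and 11 of the 54 had ratios on opposite sides of 1 with counting intervals that exclude 1. Without 2S rRNA in the totals there were 12, of which 8 were the same. Among these 8 were ctg1 (1.18 and 0.0961) and ctg18 (1.07 and 0.0988), whose deletion 2 ratios would rise to 0.682 and 0.470 with unlisted sequences at 99 reads. Ctg7 had 51172 reads in non-deleted cells, 72989 in deletion 1 (ratio 1.77) and 5468 in deletion 2 (ratio 0.146), so deletion 2 stood at 0.0829 of deletion 1. With every sequence unlisted in deletion 2 at 99 reads, its ratio to non-deleted would be 0.472 and its level 0.2675 of deletion 1. Ctg22 had 4780, 5148 and 1397 reads (ratios 1.33 and 0.400), with deletion 2 at 0.300 of deletion 1. The same filling would give 0.826, which no longer passes the limit of 0.8, and 0.619 of deletion 1.

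Ctg7 belongs to a wider pattern. Of 15 contigs with a long sense open reading frame and at least 1000 reads in non-deleted cells, 9 were more than 2-fold lower in deletion 2. Chosen by that ratio, they went together from 325801 to 43467 reads, a ratio of 0.183, against 0.962 in deletion 1 and 0.985 in the EGFP library. The totals include 2S rRNA, whose share was smallest in non-deleted cells, and this lowers each of these ratios. The sums for deletion 1 and the EGFP library were not recomputed without it. The sum for deletion 1 hides members that go both ways, from 0.292 for ctg20 to 1.77 for ctg7. The limit of 100 listed reads and the 2S rRNA share are argued against as the whole cause for the sum, since its ratio was 0.376 with every unlisted sequence at 99 reads, 0.202 with totals without 2S rRNA and 0.415 with both. The sum is carried by ctg0 and ctg17, with 215321 of the reads. With unlisted sequences at 99 reads 7 of the 9 stayed more than 2-fold lower, and 4 with 2S rRNA left out too. For ctg1 (0.682) and ctg88 (0.724) the limit of listed reads is not excluded as the main cause. A candidate explanation is a replicating RNA of another organism, such as a virus, whose level differs between cultures. In 7 of the 9 contigs the frame spans at least 90% of the contig, which a fly messenger RNA could also show, so this stays open, and no biological explanation from the design was tested.

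Tags antisense to the SV40 polyadenylation sequence, a plasmid part outside the measured RNAs, numbered 16 in the non-deleted and 5 in the deletion 1 Yb CLIP library and 0 in both untreated libraries.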

How the results depend on the processing

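Settings added after the data were seen are word lengths, 2S rRNA removal, the antisense-coding denominator, unlisted sequences at 99 reads, tags outside the block and the minimum of 1000 reads. Of the 76 recomputed values, 41 stayed within the interval of the main value or within 1.5 times a count. A reversal was defined only for the candidate's ratios, none of which crossed 1. Counts, shares, correlations and medians could not be marked as reversed. Lower Piwi contigs outnumbered higher ones under the main settings, but not with a minimum of 200 or 1000 reads or with unlisted sequences at 99 reads. The candidate's Piwi ratio was 0.308 and 0.208 in deletion 1 and deletion 2. It moved to 0.402 and 0.267 with distinct sequences, 0.354 and 0.230 without 2S rRNA in the totals, 0.381 and 0.234 with the antisense-coding contigs as denominator, 0.479 and 0.436 with unlisted sequences at 99 reads, and 0.551 and 0.482 with both that and 2S rRNA removal. With reads of 24 to 30 nt only it was 0.297 in deletion 1. Leaving out an untreated library gave the Yb ratio a range of 0.229 to 0.233 and the correlation of Yb tags with Piwi reads 0.361 to 0.370. The candidate's Yb ratio of 0.246 moved to 0.333 outside the block. The count of Piwi contigs lower in both lines, 120, became 58 with a minimum of 200 reads, 12 with 1000 and 7 with unlisted sequences at 99 reads. The higher contigs, 68, became 30 at a ratio over 4, 27 with a minimum of 1000 reads and 13 with unlisted sequences at 99 reads. Median-of-ratios scaling gave 114 lower and 80 higher, and totals without 2S rRNA 111 and 91. Fewer contigs enter at higher minimums, and a minimum of 20 reads removes nothing, since listed sequences start at 100. The Yb contigs, 68 lower and 12 higher, became 178 and 51 with a minimum of 20 tags and 21 and 1 with 200. The correlation of Yb tags with Piwi reads, 0.363, was 0.205 per kb. The share of reads with a first U was 75.5, 74.6, 75.7 and 76.4% of distinct sequences and 83.1, 81.4, 81.9 and 84.3% without 2S rRNA (non-deleted, deletion 1, deletion 2, EGFP). The median log2 ratio of the sense-coding contigs, 0.18 in deletion 1 and -2.17 in deletion 2, was 0.33 and -0.55 with unlisted sequences at 99 reads and 0.53 and -0.41 without 2S rRNA as well. The cause was not tested for the other shifts. Scaling to flam, the 3' UTR alone and the flam alternatives were not run, and distinct tags are the only CLIP unit. No paired analysis was possible because the groups compared share fewer than 2 replicate numbers. The Piwi files' limit of 100 reads sets what can be seen of low contigs.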

Other observations

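The tests in this part were chosen after the results were seen. The sense-coding contigs that were low in deletion 2 differed in the form of their small RNAs. On ctg0, a contig of 3395 nt whose frame covers 3393 nt, 95.8% of the 136791 reads in non-deleted cells were 24 to 30 nt long, 88.2% began with U, and no read ran antisense. Ctg17 had 78530 reads, 92.4% of 24 to 30 nt and 92.0% with a first U. On ctg18 54.2% were of 24 to 30 nt, on ctg72 78.5% with 12.2% at 21 nt, and on ctg20 67.0% with 33.1% beginning with U. On ctg88 61.4% began with U. Yb tags on the 9 contigs stood at a ratio of 0.625 in deletion 1 against non-deleted cells. The ratio was under 1 on 9 of 9, though that of ctg29, 0.967, had an interval of 0.862 to 1.09. Their Piwi reads in the same line stood at 0.962 with 2S rRNA in the totals. The larger 2S rRNA share of deletion 1, 25.9% against 14.8%, lowers that Piwi ratio, which was not recomputed without it.

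The fall of the candidate contig's piRNAs, by which the contig was first noticed, was set against 3 technical explanations. The limit of 100 listed reads would need a ratio near 1 once unlisted sequences are filled in, and the higher of the 2 ratios was 0.479, so this limit is argued against as the whole cause. The larger 2S rRNA share of the deletion libraries would need a ratio near 1 without it, and the higher ratio was 0.354. With both at once it was 0.551, which leaves a smaller fall. If only the bases of the block were missing, reads elsewhere would be untouched, and outside the block the higher ratio was 0.336. That these bases are missing was not shown. The block comes from the Yb tags of deletion 1, 9 of which still overlap it, and deletion 2 has no Yb library. The deletion named in the labels stays open as the cause, as a hypothesis, because each line is 1 library and the EGFP and non-deleted libraries are the only ones without it in their labels. The deletion lines also differ from these libraries in the 2S rRNA variant described next, so another difference that they share is not excluded, and the EGFP library does not control for it.

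A variant of 2S rRNA separated the libraries. The change T26C, counted from 1 at the 5′ end of the 30-nt RNA, was found at 3.97% of the reads of unchanged 2S rRNA in non-deleted cells and 3.47% in the EGFP library, but 0.0387% in deletion 1 and 0.0384% in deletion 2. The most frequent other single change, G24T, stood between 0.101 and 0.150% in all 4. A sequencing error at that position is argued against by other abundant sequences with the same base there. They showed the change in 0.0453% of reads in non-deleted cells and in no listed read of the other libraries. Changed sequences under 100 reads are not listed, so the true shares can be higher. A second source of RNA in these libraries, or a variant rRNA copy that the deletion lines lack, may account for the lowest share of 3.47%, and cannot be told apart here without a genome of the line.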
